A study of Mus musculus with 6 samples.

How the data were processed

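The series measured poly(A) RNA of plasmacytoid dendritic cells (pDCs, the bone marrow derived cells that secrete large amounts of type I interferon) from C57BL/6 mice. Per the labels' protocols, about 100000 cells per sample were sorted from bone marrow by flow cytometry as CD19-negative, CD11b-negative, CD11c-intermediate, B220-positive and PDCA-positive cells. The 6 libraries fall into 3 wild type libraries and 3 libraries from SLAMF9 knockout mice. Columns marked as knockout carry replicate numbers 1, 2 and 3. The other columns are headed admin, b3 and b4, which names neither a genotype nor a replicate. They were taken as the 3 wild type libraries because the table is headed as a comparison of knockout with wild type, and its fold changes are those of the marked columns over these 3. What the header admin stands for is not given in the sources used here.

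The deposited table holds 19496 genes with a value per library, which the authors gave as normalized counts (unit signal) with 2 decimals, that is, read counts divided by a size factor for each library. Per the file headers, the authors' table also holds a mean, a log2 fold change of knockout over wild type, a p-value and an adjusted p-value for each gene. The submitters' processing notes name cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the mouse genome build GRCm38, without saying what each was used for. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap or lie antisense to each other are uncertain. Reads that map to several places are often left out or split among copies by gene counting. Hspa1a and Hspa1b, Tgtp1 and Tgtp2, Hba-a1 and Hba-a2, the Cd209 genes, the H2 genes, the immunoglobulin light chain constant genes and Erdr1 are therefore uncertain as single genes. Gene positions were taken from GENCODE vM21 on GRCm38, in which 19398 of the 19496 gene IDs were found (99.5%).

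The low values of each library are whole multiples of the value of 1 read, from 0.889 to 1.08 normalized counts, so the reads behind each value were recovered. In every library 100% of values were whole numbers of reads within a tolerance of 0.006 normalized counts. At a step moved by 1%, at most 0.883% of the values between 20 and 200 were whole. The recovered depth was 33138602, 28557843 and 30225718 reads in the wild type columns admin, b3 and b4, and 28510779, 28967581 and 27220540 reads in knockout replicates 1, 2 and 3. A gene with 0 reads could have held up to 3 reads by counting error, which is 0.0905 to 0.110 CPM. Such floors cover counting error only, since reads copied by PCR are not independent molecules.

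The design foresaw edgeR on counts, and limma on log2 values if the table held normalized values. As it did, genes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend on mean expression) on log2(normalized count + 1), with genotype as the only term and all 6 libraries in the fit. The 13708 genes with at least 10 normalized counts in at least 3 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method over these genes. Genes with an adjusted p under 0.05 are called changed. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Levels are given as normalized counts with their SD over the libraries of a group. For a gene at 0 in every library of a group, the fold is a lower bound against 3 reads per library.

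There were 26 gene lists: the SLAM family and adaptors, genes around Slamf9 on chromosome 1, pDC identity, endosomal TLR and type I interferon induction, interferon-stimulated genes, NF-kB with cytokines and activation, the immediate early and dissociation response, migration and retention, antigen presentation, markers of conventional dendritic cells, B lineage, immunoglobulin and plasma cells, neutrophils, monocytes and macrophages, erythroid cells, T and NK cells, mast cells with basophils and megakaryocytes, early progenitors, cell cycle, apoptosis and survival, the unfolded protein response, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes and sex-linked genes. The 25 lists with at least 5 tested members were compared with all other tested genes by camera at a preset correlation between genes of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it.

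The genes named were set by a rule. Slamf9 came first. Then came the 12 genes with the largest log2 fold change in each direction among genes with an assigned name that passed the adjusted p of 0.05, had a mean of at least 1 CPM of recovered reads and did not overlap between the groups. Of each list, up to 4 passing members with the smallest p were taken, and members with the smallest p filled up to 2 where fewer passed. Genes outside the rule are marked as chosen after their values were seen. The groups, the test with its fallback, the lists, this rule and most alternatives were fixed before the data were examined.

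The scripts were tested on simulated reads drawn for the real genes and depths, with 200 genes changed by known folds in the comparison of knockout with wild type. Of 13735 simulated genes tested with limma, 7 were called falsely, which was 3.6% of all calls. The limma step recovered 58 of 67 genes changed by 1.5-fold (86.6%), 66 of 67 changed by 2-fold and 66 of 66 changed by 4-fold. The changed genes were drawn from those with a mean of at least 50 normalized counts, so recovery at lower levels was not tested. In simulated data with no change, limma called 0 of 13761 genes and edgeR called 0 of 13722 genes. Over 27 simulated lists, camera and fry found 2 of 2 shifted lists and called 0 of the others. The simulated genes varied independently of each other, so this could not show false calls for lists whose genes move together. In the real lists the estimated correlation reached 0.70 for interferon-stimulated genes and 0.82 for cytosolic ribosomal proteins.

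Alternatives were library totals in place of size factors, TMM factors, other filters, pseudocounts of 0.5 and 5, the count tests edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads, edgeR's robust fit (with statmod 1.5.0), a test against a 1.5-fold change and leaving out each library in turn. edgeR's quasi-likelihood test with TMM on the recovered reads called 1168 genes, of which 1143 were also called by limma. Every library was compared with every other by a chi-square over genes on the recovered reads. Within groups the statistic was 7.19 to 13.8 times its degrees of freedom, and between groups 14.4 to 43.3 times, so no pair of libraries agreed within sampling noise. All 6 libraries were used, and 0 columns of other samples were left out.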

Results

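Bulk RNA-seq was available for plasmacytoid dendritic cells (pDCs) sorted from mouse bone marrow, in 3 wild type libraries and 3 libraries from SLAMF9 knockout mice of the C57BL/6 strain. The headers of the wild type columns name no genotype, so that group was inferred from the other columns being marked as knockout. The comparison asks which transcripts differ in pDCs when SLAMF9, a cell surface receptor of the SLAM family, is lost. The recovered depth was 27220540 to 33138602 reads per library, and 17108 to 17465 genes had a value above 0. The labels call the libraries triplicates without saying that they came from separate animals, so p-values measure only the spread between these libraries, which may be technical. On the first principal component, which held 43.8% of the variance, the wild type libraries lay at -28.0, -20.9 and -14.1 and the knockout libraries at 20.2, 16.5 and 26.4. The second component (16.2%) set knockout replicate 3, at 23.3, apart from knockout replicates 1 and 2, at -13.9 and -14.6. The Y-linked genes Eif2s3y and Kdm5d were measured in all 6 libraries, with 2363 ± 178 (SD, n = 3) against 2291 ± 32.3 (SD, n = 3) and 1579 ± 98.9 (SD, n = 3) against 1610 ± 78.2 (SD, n = 3) normalized counts in wild type and knockout. Of the 4 sex-linked genes tested with limma, 0 passed, 0 passed adjusted over the list alone, 0 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 0.

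Slamf9 itself (ENSMUSG00000026548), a gene of 4 exons on the plus strand of chromosome 1 from 172475358 to 172478575 (GRCm38), fell in the knockout but was still read. The wild type libraries held 1747, 1894 and 2420 normalized counts, and knockout replicates 1, 2 and 3 held 745, 680 and 812. The means were 2020 ± 354 (SD, n = 3) and 746 ± 66.0 (SD, n = 3), so the knockout kept 36.9% of the wild type level (log2 fold change -1.43, SE 0.105, limma with Benjamini-Hochberg adjusted p = 7.55e-06). The authors' deposited table gives a log2 fold change of -1.44 with an adjusted p of 1.74e-36 for Slamf9. The altered exons are not given in the sources used here, and the values count reads over the whole gene. They therefore cannot show whether the remaining reads come from an altered transcript.

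The gene next to Slamf9 rose. Igsf9 (ENSMUSG00000037995), an immunoglobulin superfamily adhesion gene that starts 3.2 kb downstream on the same strand (chromosome 1, 172481788 to 172498878), went from 461 ± 106 (SD, n = 3) to 1086 ± 137 (SD, n = 3) normalized counts, a log2 fold change of 1.25 (SE 0.135, limma adjusted p = 1.03e-04). On the other side, the pseudogene Gm7804 (chromosome 1, 172458569 to 172474969), chosen after its values were seen, rose from 7.41 ± 1.3 (SD, n = 3) to 24.7 ± 3.89 (SD, n = 3), a log2 fold change of 1.61 (SE 0.358, limma adjusted p = 0.0129). Among 48 tested genes of the list around Slamf9, 2 rose, 6 fell and 40 did not pass, against 4 and 7 adjusted over the list alone. Cd244, a SLAM family receptor of NK cells, rose (log2 fold change 0.63, SE 0.0961, limma adjusted p = 0.00119), while the nectin gene Pvrl4 (-0.47, limma adjusted p = 8.73e-04) and the tetraspanin partner Igsf8 (-0.35, limma adjusted p = 0.00146) fell. Of 9 tested members of the SLAM family and adaptors, 2 rose and 6 did not pass, and Slamf9 fell. Adjusted over the list alone, 3 rose and 1 fell. The SLAM adaptor gene Sh2d1b1 went from 203 ± 28.4 (SD, n = 3) to 343 ± 19.6 (SD, n = 3). Neither list shifted as a whole by camera (adjusted p = 0.183 for the SLAM family and 0.339 for the neighbours).

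**Figure D1:**
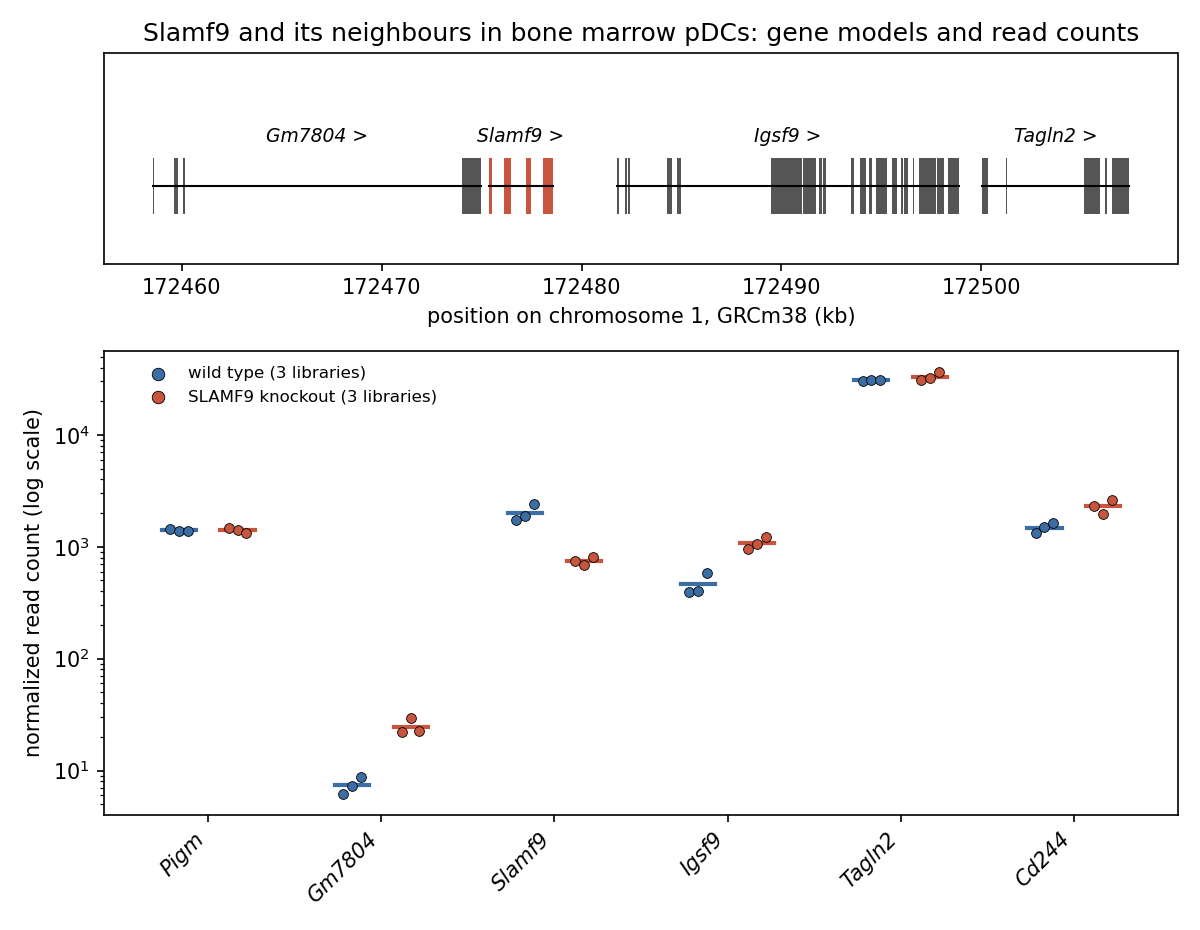
Gene models of Slamf9 and its neighbours on chromosome 1 (position in kb, GRCm38, boxes are exons of all annotated transcripts) above the normalized read count of each library on a log scale, with bars at the group means of 3 libraries. Knockout libraries lay below wild type for Slamf9 (680 to 812 against 1747 to 2420) and above it for Igsf9, Gm7804 and Cd244, while Pigm and Tagln2, chosen after their values were seen, did not pass the test (limma adjusted p = 0.960 and 0.415).

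Across the transcriptome, 1178 of 13708 tested genes changed (8.59%), of which 499 were higher and 679 lower in the knockout. Most changes were small: 954 of the changed genes (81.0%) moved by less than 2-fold, and the median absolute log2 fold change was 0.46. Among changed genes, 56 were at least 2-fold higher and 168 at least 2-fold lower, and 7 and 37 changed by at least 4-fold. The libraries of the groups did not overlap for 3662 tested genes (26.7%), where chance gives 10%. The authors' deposited table calls 1225 genes, 531 higher and 694 lower, and 1107 genes were called by both. Without the wild type library admin, without b3 or without knockout replicate 1, the count of changed genes dropped to 658, 676 and 713.

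The heat shock protein genes Hspa1a and Hspa1b, which encode the stress-inducible chaperone HSP70, showed large increases. Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) went from 4.50 ± 0.62 (SD, n = 3) to 183 ± 12.7 (SD, n = 3) normalized counts, a log2 fold change of 5.07 (SE 0.255, limma adjusted p = 6.12e-07). Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) went from 93.3 ± 51.4 (SD, n = 3) to 1131 ± 143 (SD, n = 3), a log2 fold change of 3.71 (SE 0.265, limma adjusted p = 7.55e-06). The copies share much sequence, and their sum went from 97.8 ± 51.0 (SD, n = 3) to 1314 ± 153 (SD, n = 3). Ddit4, an inhibitor of mTORC1 induced by stress and glucocorticoids, rose from 752 ± 47.6 (SD, n = 3) to 2116 ± 455 (SD, n = 3), and the complement gene C8a rose from 47.8 ± 8.58 (SD, n = 3) to 186 ± 21.3 (SD, n = 3). The synaptic adhesion gene Nrxn2 rose with a log2 fold change of 1.74, and the C-type lectin genes Cd209c and Cd209d rose by 1.63 and 1.48 (limma adjusted p = 4.54e-04, 0.0146 and 0.00372). Cd209c missed the threshold with DESeq2 (adjusted p = 0.0798) and without knockout replicate 1 or 3 (limma adjusted p = 0.0857 and 0.0609). The B cell surface genes Cd19 and Ms4a1 rose from low levels, 23.5 ± 9.13 (SD, n = 3) to 74.2 ± 19.2 (SD, n = 3) and 17.7 ± 7.03 (SD, n = 3) to 51.7 ± 14.2 (SD, n = 3). Ms4a1 was not called without knockout replicate 1 (limma adjusted p = 0.0808). Erdr1, in the repeated pseudoautosomal region, was at 0 in every wild type library and at 15.2, 11.1 and 156 in the knockout libraries, at least 21.03-fold higher when set against 3 reads per library (limma adjusted p = 0.00212). That bound rests on knockout replicate 3 and was 4.53-fold without it. Rps6kl1 held 362, 216 and 33.4 normalized counts in knockout replicates 1, 2 and 3 against 19.7 ± 8.66 (SD, n = 3) in wild type (log2 fold change 2.86, SE 0.647, limma adjusted p = 0.0145), and its call was lost without wild type b3, knockout replicate 1 or knockout replicate 2 (adjusted p = 0.0643, 0.0965 and 0.0620). Leaving out a library moved the log2 fold change from 2.17 to 3.87 for Rps6kl1, 3.40 to 4.13 for Hspa1b, 1.41 to 2.05 for Nrxn2, 1.09 to 2.00 for Cd209c and 1.08 to 1.76 for Cd209d. Tgtp1, an interferon-inducible GTPase gene, rose by 2.00 on the log2 scale, but summed with its near-identical copy Tgtp2, chosen after its values were seen, the level went from 851 ± 85.2 (SD, n = 3) to 516 ± 86.0 (SD, n = 3).

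The genes with the largest decreases included secreted and surface proteins. Spon1 (ENSMUSG00000038156, chromosome 7, 113765998 to 114043370), an extracellular matrix protein gene, went from 1571 ± 859 (SD, n = 3) to 99.3 ± 56.9 (SD, n = 3) normalized counts, a log2 fold change of -4.02 (SE 0.460, limma adjusted p = 1.50e-04). Procr, the endothelial protein C receptor gene, went from 803 ± 187 (SD, n = 3) to 135 ± 34.2 (SD, n = 3), a log2 fold change of -2.57 (SE 0.194, limma adjusted p = 9.10e-06). The sialyltransferase gene St8sia6 went from 785 ± 161 (SD, n = 3) to 102 ± 40.4 (SD, n = 3), and Lta, which encodes the cytokine lymphotoxin alpha, from 363 ± 194 (SD, n = 3) to 49.9 ± 9.59 (SD, n = 3). The transporter gene Abcc6 (log2 fold change -3.74), the growth factor binding protein gene Igfbp7 (-3.52), the artemin receptor gene Gfra3 (-3.45) and the neuropeptide receptor gene Vipr2 (-3.26) fell. So did the potassium channel interacting protein gene Kcnip3 (-2.74), the semaphorin gene Sema6d (-2.58), Ankrd33b (-2.48) and Rasal1, a Ras GTPase activator gene (-2.47), with limma adjusted p of 3.67e-05 to 3.51e-04 over these 8 genes. The wild type libraries also differed in several of these genes, as for Spon1 with 2425, 1581 and 707 normalized counts. Over the fits that left out a library, the log2 fold change ran from -4.51 to -3.41 for Spon1, -4.10 to -3.12 for Abcc6, -3.99 to -3.12 for Igfbp7, -3.82 to -2.89 for Gfra3 and -3.63 to -2.97 for Vipr2. It ran from -3.25 to -2.64 for St8sia6, -3.06 to -2.32 for Lta and -2.87 to -2.22 for Sema6d. Abcc6 was at 7.08, 6.04 and 1.08 normalized counts in the knockout libraries, so its fold rests on few reads.

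**Figure D2:**
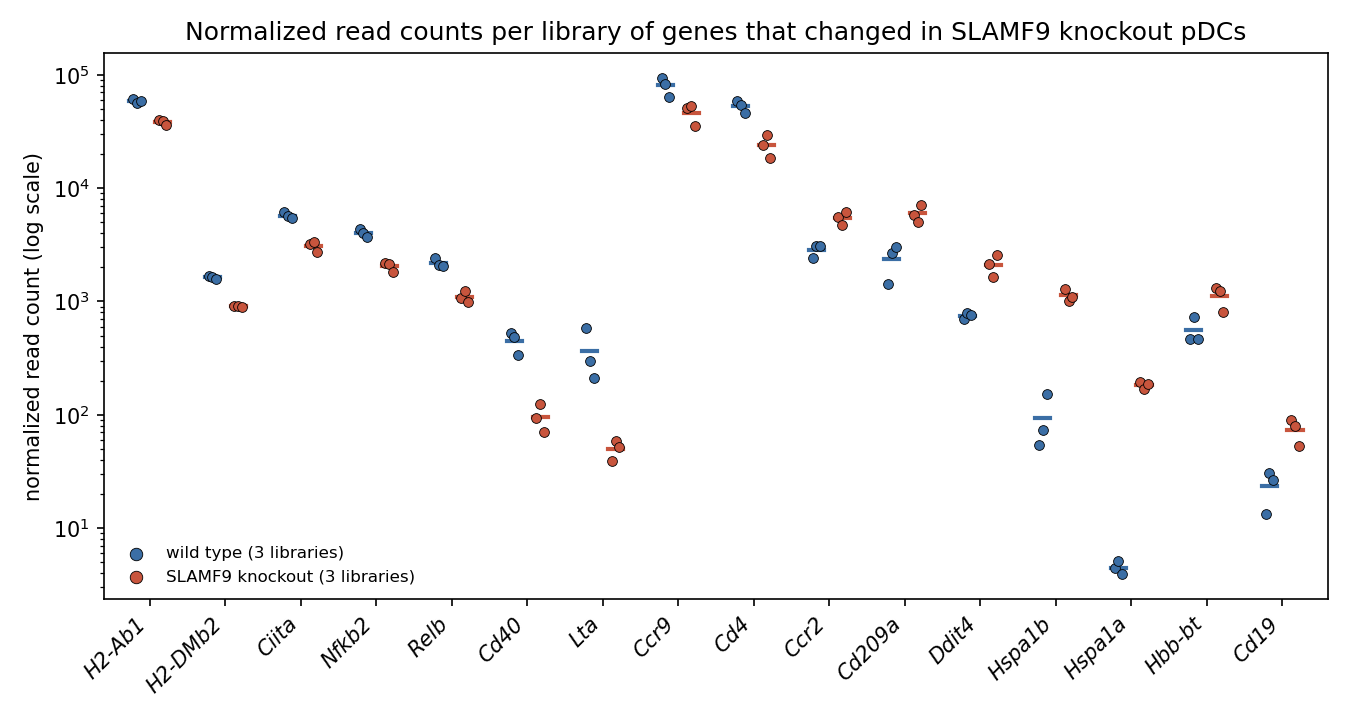
Normalized read count (log scale) of 16 changed genes in each of the 3 wild type and 3 SLAMF9 knockout libraries, with bars at the group means. The groups did not overlap for any gene shown, which was also so for 1166 of all 1178 changed genes and was a condition for naming some of them. H2-Ab1 was at 58675 against 38323 on average, and Hspa1a at 4.50 against 183.

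Genes of antigen presentation fell together. Of 23 tested members, 19 fell and 4 did not pass, and adjusted over the list alone 20 fell and 1 rose. Ciita, the master transcription factor of MHC class II genes, went from 5717 ± 348 (SD, n = 3) to 3079 ± 324 (SD, n = 3) normalized counts (log2 fold change -0.90, SE 0.0732, limma adjusted p = 1.51e-05). The MHC class II gene H2-Ab1 went from 58675 ± 2237 (SD, n = 3) to 38323 ± 1807 (SD, n = 3), a log2 fold change of -0.61. The MHC class II related genes H2-DMb2 (-0.84, limma adjusted p = 7.41e-06) and H2-Ob (-0.90, limma adjusted p = 9.26e-05) fell as well. The list shifted down by camera (adjusted p = 2.95e-18), with adjusted p = 0.318 with an estimated correlation.

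Of 22 tested NF-kB, cytokine and activation genes, 12 fell and 10 did not pass, and 18 fell adjusted over the list alone. Nfkb2 and Relb, subunits of the non-canonical NF-kB pathway, went from 4011 ± 336 (SD, n = 3) to 2048 ± 207 (SD, n = 3) and from 2203 ± 208 (SD, n = 3) to 1095 ± 126 (SD, n = 3), log2 fold changes of -0.97 and -1.01 (limma adjusted p = 1.47e-05 and 2.05e-05). The costimulatory receptor gene Cd40 went from 453 ± 99.4 (SD, n = 3) to 96.0 ± 27.5 (SD, n = 3), a log2 fold change of -2.24 (SE 0.205, limma adjusted p = 3.31e-05). Nfkbie, an inhibitor of NF-kB, fell by 0.63 on the log2 scale. The list shifted down by camera (adjusted p = 2.38e-16), with adjusted p = 0.318 with an estimated correlation.

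Among 35 tested interferon-stimulated genes, 10 fell and 25 did not pass, and 16 fell adjusted over the list alone. The chemokine gene Cxcl10 went from 72.0 ± 8.51 (SD, n = 3) to 24.0 ± 5.61 (SD, n = 3) normalized counts (log2 fold change -1.56, SE 0.247, limma adjusted p = 0.00146). The antiviral gene Ifit1 and the RNA sensor gene Ifih1 fell by 1.10 and 0.74 on the log2 scale, and Oasl1, a translational inhibitor of Irf7, fell by 0.69. The list shifted down by camera (adjusted p = 1.68e-07), with adjusted p = 0.602 with an estimated correlation. Its mean log2 level relative to wild type was -0.42 and -0.59 in knockout replicates 1 and 3 but -0.019 in replicate 2, where the wild type libraries lay from -0.015 to 0.009.

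The pDC identity list moved in both directions: 5 of 33 tested members rose, 8 fell and 20 did not pass, against 10 and 9 adjusted over the list alone. Lag3, an inhibitory receptor gene, went from 22429 ± 2022 (SD, n = 3) to 14783 ± 1297 (SD, n = 3) normalized counts, and the phospholipid transfer protein gene Pltp and the kallikrein gene Klk1 fell with log2 fold changes of -0.55 and -0.79. Dntt, the terminal transferase gene, rose by 0.46. Irf8, the transcription factor gene with the highest level in the list and chosen after its values were seen, was at 184581 ± 2122 (SD, n = 3) and 177149 ± 6095 (SD, n = 3) and did not pass (limma adjusted p = 0.714). The list did not shift by camera (adjusted p = 0.737). Among 24 tested genes of endosomal TLR signalling and type I interferon induction, 1 rose, 2 fell and 21 did not pass, against 3 and 2 adjusted over the list alone, and camera gave an adjusted p of 0.819. Tlr9, the sensor of CpG DNA, went from 14026 ± 684 (SD, n = 3) to 11815 ± 1041 (SD, n = 3) (log2 fold change -0.25, SE 0.0647, limma adjusted p = 0.0300), and the adaptor gene Traf3 fell by 0.41. Hps3, a gene of lysosome-related organelle biogenesis, rose by 0.20, and the calls of Tlr9 and Hps3 were each lost in 5 of 6 fits that left out a library, with the highest adjusted p at 0.126 without knockout replicate 1 for Tlr9 and 0.196 without wild type admin for Hps3.

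Chemokine receptor genes changed in opposite directions. Ccr2 and Ccr5, receptors for inflammatory chemokines, rose from 2847 ± 379 (SD, n = 3) to 5488 ± 708 (SD, n = 3) and from 5544 ± 1281 (SD, n = 3) to 8623 ± 277 (SD, n = 3) normalized counts. Ccr9, the gut homing receptor gene, fell from 80483 ± 15364 (SD, n = 3) to 46446 ± 9964 (SD, n = 3), and Ccr7, the lymph node homing receptor gene, fell from 443 ± 56.2 (SD, n = 3) to 287 ± 31.2 (SD, n = 3). Their log2 fold changes were 0.95, 0.66, -0.80 and -0.62 (limma adjusted p = 9.26e-05, 0.00376, 0.00501 and 0.00479). Of 23 tested migration and retention genes, 5 rose, 3 fell and 15 did not pass, against 8 and 4 adjusted over the list alone, and the list did not shift by camera (adjusted p = 0.0713) but was called higher in 4 of 13 settings: with no filter, with the stricter filter, and without wild type admin or b4 (adjusted p = 0.0458, 0.0390, 0.0257 and 0.0449). Fry called it higher as well (adjusted p = 0.0180), and camera with an estimated correlation did not (adjusted p = 0.318).

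The early progenitor list shifted down by camera (adjusted p = 0.0205), with adjusted p = 0.318 with an estimated correlation. Of 17 tested members, 4 fell and 13 did not pass, and 5 fell adjusted over the list alone. The stem cell factor receptor gene Kit went from 956 ± 82.1 (SD, n = 3) to 409 ± 20.4 (SD, n = 3) (log2 fold change -1.22, SE 0.0842, limma adjusted p = 7.41e-06). Ly6a, which encodes the surface antigen Sca-1, went from 18735 ± 1212 (SD, n = 3) to 10401 ± 2165 (SD, n = 3), the growth factor gene Csf1 fell by 0.83 on the log2 scale and the transcription factor gene Myb by 0.22. The Myb call was lost in 3 of 6 fits that left out a library. Without knockout replicate 1 the list missed the threshold (camera adjusted p = 0.0525). Among 22 tested apoptosis and survival genes, 2 rose, 2 fell and 18 did not pass, against 2 and 3 adjusted over the list alone. Cdkn1a, a cell cycle inhibitor gene, and Pmaip1, a pro-apoptotic BH3-only gene, fell with log2 fold changes of -1.71 and -0.87, and the survival gene Bcl2 and the apoptosome gene Apaf1 rose by 0.43 and 0.20. The Apaf1 call was lost in 3 of 6 fits that left out a library. That list's median was 0.01 and its mean -0.14, so they differed in sign, and camera gave an adjusted p of 0.557.

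Genes listed as markers of other bone marrow cells also moved with genotype, though many were at high levels in these sorted cells. Wild type means reached 1000 normalized counts for 2 of 16 erythroid, 8 of 22 B lineage and 7 of 14 immunoglobulin genes. The same held for 5 of 21 T and NK cell and 9 of 20 conventional dendritic cell genes. Bulk values cannot tell a change within pDCs from a change in the share of other cells. Of 16 tested erythroid genes, 10 rose and 6 did not pass, and 15 rose adjusted over the list alone. The haemoglobin genes Hba-a1 and Hbb-bt went from 1185 ± 273 (SD, n = 3) to 2183 ± 460 (SD, n = 3) and from 558 ± 150 (SD, n = 3) to 1117 ± 268 (SD, n = 3) normalized counts, and the band 3 anion exchanger gene Slc4a1 and the erythroblast gene Ermap rose by 0.98 and 0.83 on the log2 scale. The erythroid list shifted up by camera (adjusted p = 1.91e-11), with adjusted p = 0.318 with an estimated correlation. Of 22 tested B lineage genes, 6 rose, 3 fell and 13 did not pass, against 10 and 3 adjusted over the list alone. The IgM receptor gene Fcmr and the B cell receptor gene Cd79a rose by 1.18 and 0.89, the latter not called without knockout replicate 1 (limma adjusted p = 0.0559), while Fcrla, an Fc receptor-like gene at a high level in these cells, fell from 12714 ± 126 (SD, n = 3) to 9790 ± 133 (SD, n = 3). The other falling members, chosen after their values were seen, were Cd79b (-0.27) and the surrogate light chain gene Igll1 (-1.19). The B lineage list shifted up by camera (adjusted p = 0.0173), with adjusted p = 0.318 with an estimated correlation.

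Of 14 tested immunoglobulin and plasma cell genes, 5 fell and 9 did not pass, and 5 fell adjusted over the list alone. The light chain constant gene Igkc went from 6967 ± 1409 (SD, n = 3) to 2322 ± 221 (SD, n = 3) normalized counts (log2 fold change -1.57, SE 0.115, limma adjusted p = 7.55e-06). Iglc2, Iglc3 and the endoplasmic reticulum gene Derl3 fell by 1.13, 0.43 and 0.72 on the log2 scale, with the light chain copies uncertain as single genes. The mean log2 level of the list overlapped between the genotypes, with knockout replicate 1 at -0.068 and wild type b4 at -0.177. The list shifted down by camera (adjusted p = 0.00529), with adjusted p = 0.318 with an estimated correlation. Of 21 tested T and NK cell genes, 1 rose, 3 fell and 17 did not pass, against 3 and 9 adjusted over the list alone. Cd4, which mouse pDCs themselves express, fell from 52958 ± 6829 (SD, n = 3) to 24037 ± 5536 (SD, n = 3), Cd8b1 and the perforin gene Prf1 fell with log2 fold changes of -1.05 and -1.04, and the NK receptor gene Klrd1 rose by 0.57. The Prf1 call was lost in 3 of 6 fits that left out a library. The list shifted down by camera (adjusted p = 0.00234), with adjusted p = 0.578 with an estimated correlation, and its mean log2 level overlapped as well (wild type b3 at -0.462, knockout replicate 1 at -0.26).

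Of 20 tested conventional dendritic cell genes, 2 rose, 2 fell and 16 did not pass, against 3 and 2 adjusted over the list alone, and camera gave an adjusted p of 0.642. Fscn1, an actin bundling gene of mature dendritic cells, went from 473 ± 50.2 (SD, n = 3) to 156 ± 9.43 (SD, n = 3) normalized counts (log2 fold change -1.59, SE 0.115, limma adjusted p = 7.55e-06), and Cd8a fell from 10127 ± 2802 (SD, n = 3) to 3920 ± 1061 (SD, n = 3). The lectin gene Cd209a and the transcription factor gene Irf4 rose by 1.40 and 0.37 on the log2 scale. Among 22 tested monocyte and macrophage genes, 2 rose, 1 fell and 19 did not pass, with 2 and 1 adjusted over the list alone and a camera adjusted p of 0.488. The apolipoprotein gene Apoe and the coagulation factor gene F13a1 rose by 0.71 and 0.62, and the scavenger receptor gene Cd163 fell by 0.70. The F13a1 call was lost in 2 of 6 fits that left out a library. Of 19 tested neutrophil lineage genes, the myeloperoxidase gene Mpo rose (log2 fold change 0.43, limma adjusted p = 0.0498) and 18 did not pass, among them Elane (0.43, limma adjusted p = 0.0655). The Mpo call was lost in 4 of 6 fits that left out a library (highest limma adjusted p = 0.214), and its libraries overlapped between the genotypes. For that list limma called 0 genes adjusted over the list alone, 4 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 1. It shifted up by camera (adjusted p = 0.00307), with adjusted p = 0.622 with an estimated correlation and 0.475 without knockout replicate 1, and knockout replicate 3 (-0.131) lay below wild type b3 (0.185) in its mean log2 level. None of 6 tested mast cell, basophil and megakaryocyte genes passed in limma (0 adjusted over the list alone, 0 with an unadjusted p under 0.05, and 0 each by edgeR and DESeq2). Hdc was at 41.1 ± 5.25 (SD, n = 3) and 58.4 ± 17.6 (SD, n = 3), Cpa3 at 12.2 ± 5.58 (SD, n = 3) and 24.7 ± 18.1 (SD, n = 3), and camera gave an adjusted p of 0.214.

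**Figure D3:**
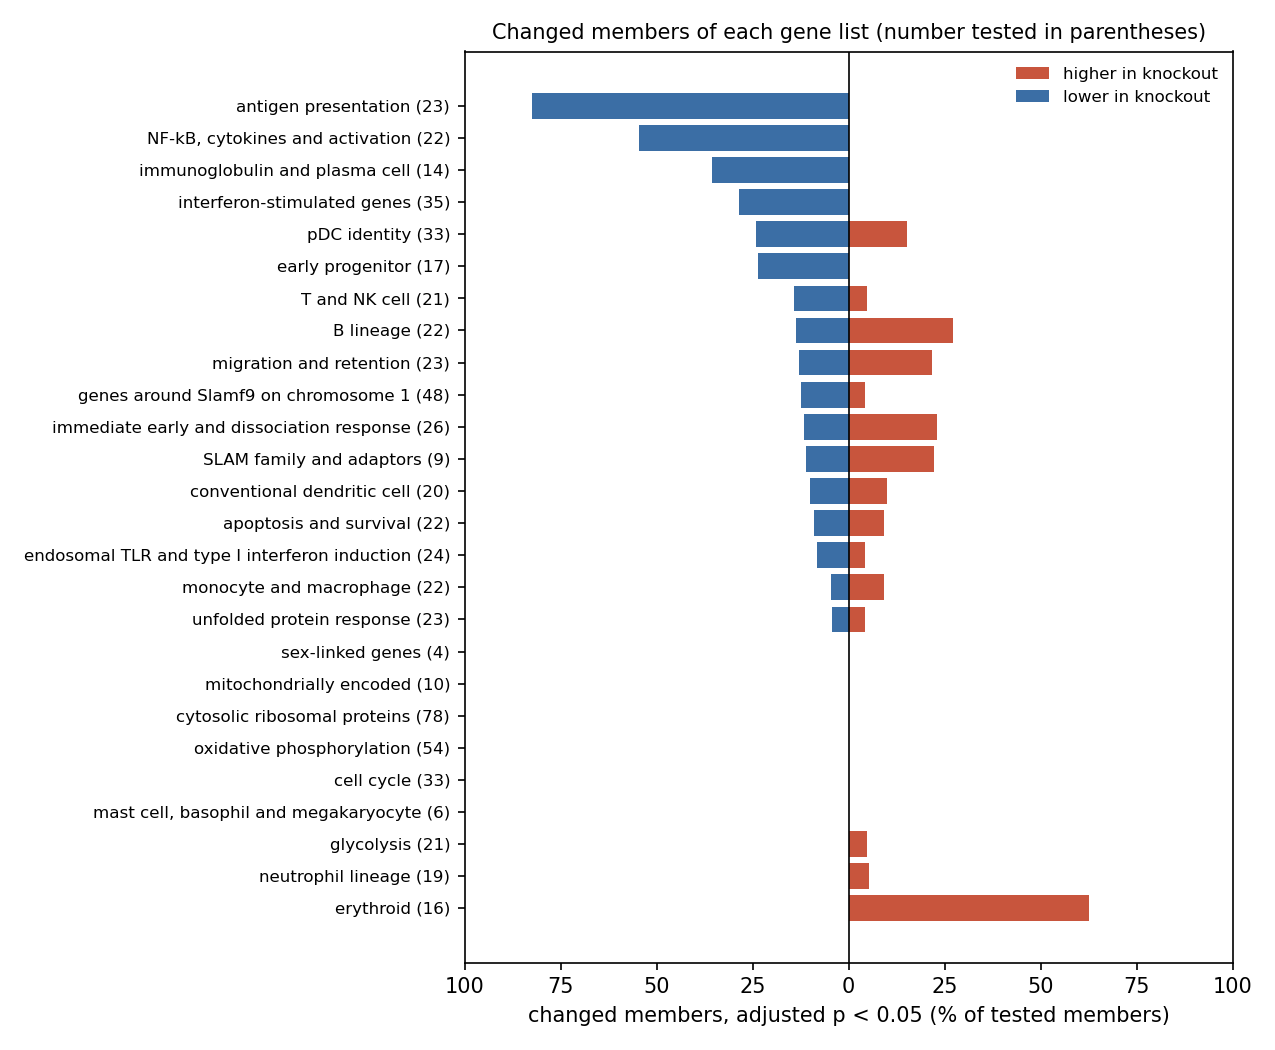
Share of the tested members of each gene list that changed (limma adjusted p under 0.05), as percent of the list, with members lower in the knockout drawn to the left and members higher in the knockout to the right. Antigen presentation (19 of 23 lower), NF-kB (12 of 22 lower) and erythroid genes (10 of 16 higher) had the largest shares in one direction.

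In the immediate early and dissociation response list, 6 of 26 tested genes rose, 3 fell and 17 did not pass, against 7 and 3 adjusted over the list alone. Beside Hspa1a and Hspa1b, the chaperone gene Hsph1 rose from 740 ± 76.2 (SD, n = 3) to 1114 ± 58.9 (SD, n = 3) normalized counts, and the AP-1 gene Fos rose from 179 ± 31.5 (SD, n = 3) to 474 ± 213 (SD, n = 3). For Fos this was a log2 fold change of 0.98 to 1.61 over the fits that left out a library. Jund, Klf2 and Atf3 fell, which were named after their values were seen. The list shifted up by camera (adjusted p = 0.0173), with adjusted p = 0.484 with an estimated correlation, and its call was lost without wild type b3, without knockout replicate 3 and without the 2 outermost libraries (camera adjusted p = 0.0570, 0.177 and 0.0576). Of the 26 members 19 had a positive log2 fold change, with a median of 0.09 and a mean of 0.39. That mean includes the similar copies Hspa1a (5.07) and Hspa1b (3.71), and camera was not run without them. Among 23 tested unfolded protein response genes, 1 rose, 1 fell and 21 did not pass, with 1 and 1 adjusted over the list alone and a camera adjusted p of 0.201. Without knockout replicate 3, and without the 2 outermost libraries, that list was called higher (camera adjusted p = 0.0104 and 0.00427), with adjusted p = 0.744 for all libraries with an estimated correlation. Herpud1 fell by 0.28 and Dnajb9 rose by 0.22 on the log2 scale. The Dnajb9 call was lost in 5 of 6 fits that left out a library (highest limma adjusted p = 0.194). Of 21 tested glycolysis genes, the lactate dehydrogenase gene Ldhb rose (log2 fold change 0.40, limma adjusted p = 0.00709), also adjusted over the list alone, and 20 did not pass, among them Hk3 (0.66, limma adjusted p = 0.0648). Without knockout replicate 1 the Ldhb call was lost (limma adjusted p = 0.0508). Camera gave an adjusted p of 0.557.

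Among genes of basic cell functions, limma called none in the 4 lists tested, though other tests called mitochondrially encoded genes. Of 33 tested cell cycle genes limma called 0 (0 adjusted over the list alone), 4 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 0, with Tk1 at -0.19 and Aurkb at 0.17 on the log2 scale and a camera adjusted p of 0.177. Of 54 oxidative phosphorylation genes limma called 0 (0 adjusted over the list alone), 3 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 0, with Sdha at 0.15 and Cox7b at -0.13 and a camera adjusted p of 0.214. Of 78 cytosolic ribosomal protein genes limma called 0 (0 adjusted over the list alone), 3 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 0, with Rpl29 at -0.14 and Rps24 at -0.17 and a camera adjusted p of 0.0668. The calls and directions of these 3 lists changed between settings, and each had an adjusted p of 0.791 with an estimated correlation. The ribosomal list was called lower without wild type b4, knockout replicate 1 or knockout replicate 3 (camera adjusted p = 6.64e-05, 0.0204 and 2.07e-06) and turned upward without knockout replicate 2 (0.156). It was also called lower with no filter (0.0321) and without the 2 outermost libraries (0.000117). The oxidative phosphorylation list was called lower without b4 or knockout replicate 3 (0.00565 and 0.0272) and turned upward without knockout replicate 2 (0.524). The cell cycle list was called higher without admin or knockout replicate 2 (0.0136 and 0.00886) and turned downward without b4 (0.925). Of 10 mitochondrially encoded genes limma called 0, 4 had an unadjusted p under 0.05 and were lower adjusted over the list alone, and edgeR called 2 and DESeq2 4. Among them mt-Rnr2 was at -0.27 (limma adjusted p = 0.0549) and mt-Nd2 at -0.29 (limma adjusted p = 0.0584). That list shifted down by camera (adjusted p = 0.00570), with adjusted p = 0.578 with an estimated correlation and 0.0762 without knockout replicate 1, and knockout replicate 3 (-0.049) lay above wild type b4 (-0.098) in its mean log2 level. Across the 25 lists tested, camera called 4 higher and 7 lower at its preset correlation, and 0 with an estimated correlation (2 lists, antigen presentation and NF-kB, had an unadjusted p under 0.05), while fry called 5. Of the 102 named genes, which include those that had no call to lose, 24 lost their call in edgeR's robust fit, among them Spon1, Nrxn2, Fos, Ccr5, Ccr9, Cd4, Cd8a, Cd209a, Hba-a1 and Slc4a1.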

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

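The TMM scaling of the list and limma results, edgeR with TMM on recovered reads, the fit without 2 libraries, and the 0.5 and 5 pseudocounts for Slamf9 and the lists were chosen after the data were seen. Slamf9 was lower in all 20 alternatives, from -1.59 to -1.29 on the log2 scale, and from -1.52 to -1.29 when each library was left out in turn. The count of changed genes, 1178, was 1085 to 1338 with other scalings, filters, pseudocounts and count tests, and edgeR, which gave 1168, shared 1143 genes with it. With library totals in place of size factors, 607 genes were higher and 622 lower (49.4% higher against 42.4%). Testing against a 1.5-fold change left 107 genes, 17 higher and 90 lower, since that test excludes small changes. Leaving out each library in turn gave 658 to 1253 genes. The lowest counts came without wild type admin (658), wild type b3 (676) and knockout replicate 1 (713), and 672 genes changed without admin and knockout replicate 3 together. Fewer libraries were fitted there, and no other cause was tested. No paired analysis was possible because the wild type columns carry no replicate number.

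Of the 25 lists tested, 11 shifted by camera, 0 did so with an estimated correlation (2 at an unadjusted p under 0.05, smallest adjusted p = 0.318), and fry called 5, namely antigen presentation, NF-kB, immunoglobulin, early progenitor and migration genes. Other scalings, filters and pseudocounts gave 11 to 13 lists, and leaving out a library gave 9 to 14. The NF-kB, antigen presentation, interferon-stimulated, erythroid, B lineage, immunoglobulin and T and NK cell lists were called in 13 of 13 settings with the preset correlation.

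Of 102 named genes, 24 lost their call in edgeR's robust fit and 54 in the test against a 1.5-fold change. The 102 include genes that did not pass in the main test, such as Elane and Tk1, and so had no call to lose. In fits that left out a library, calls were lost in at least 1 fit for Rps6kl1, Cd209c, Ms4a1, Tlr9, Hps3, Cd79a, Mpo, F13a1, Prf1, Myb, Apaf1, Dnajb9 and Ldhb, 13 genes, all of them without knockout replicate 1. The adjusted p there was 0.0508 for Ldhb, 0.0559 for Cd79a, 0.0808 for Ms4a1 and 0.214 for Mpo. The Y-linked genes, which never passed, turned in sign: Eif2s3y ran from -0.104 to 0.001 over the fits that left out a library, with 0.001 without wild type b3, and Kdm5d from -0.018 without b3 to 0.073, with -0.009 without knockout replicate 2. Genes near 10 normalized counts, such as Hspa1a in wild type, rest on few reads.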

Other observations

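The genes of this paragraph and the tests of B cells, conventional dendritic cells, shared reads, heat shock genes, chromosome 17, flanking DNA and the local allele were chosen after the results were seen. For the B cell and conventional dendritic cell tests, the requirements that a list shift up, and that immunoglobulin genes not shift down, before a loss is argued against were added once these shifts were known. Several genes outside the lists changed at high levels. Plaur, the urokinase receptor gene, fell from 14935 ± 3543 (SD, n = 3) to 5032 ± 1244 (SD, n = 3) normalized counts, and Cd44, the hyaluronan receptor gene, from 28989 ± 3948 (SD, n = 3) to 17247 ± 2481 (SD, n = 3) (limma adjusted p = 9.42e-05 and 5.88e-04). Hsd11b1, whose enzyme activates glucocorticoids, fell with a log2 fold change of -1.50, the lymphotoxin beta gene Ltb with -1.48 and Il2rg, the common cytokine receptor gamma chain gene, with -0.77. Among genes that rose, the receptor genes Cd28 and Btla had log2 fold changes of 1.00 and 0.87, and Tsc22d3, a glucocorticoid-induced gene, went from 2059 ± 96.6 (SD, n = 3) to 3972 ± 637 (SD, n = 3) (limma adjusted p = 6.08e-05).

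The split of the 6 libraries by genotype gave 1178 changed genes, and the highest of the other 9 splits gave 0 in limma, with 153 to 850 genes at an unadjusted p under 0.05 against 2996, and 0 in edgeR. For the lists the split by genotype gave 11, the highest other split also gave 11, and 3 of the 10 splits gave as many. With 10 splits the share that give as much (1 of 10 for genes) is never under 0.1, so they are too few for a share under 0.05. Each other split also mixes the genotypes within its groups. Any difference between the genotypes, whatever its cause, then adds to the spread within groups and lowers the number of genes called. The counts of the other splits are therefore no measure of noise.

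Antigen presentation and NF-kB genes were lower in the knockout. The tables argue against GC content and length, since 29 of the 31 called genes of both lists kept their call after that trend was removed, with their median moving from -0.581 to -0.564. A loss of B cells remains open: the B lineage list shifted up with Cd19, Ms4a1 and Cd79a (median log2 fold change 0.169, camera adjusted p = 0.0173), while the immunoglobulin list shifted down with Igkc (camera adjusted p = 0.00529), Fcrla, Cd79b and Igll1 fell, and both shifts had adjusted p = 0.318 with an estimated correlation. A loss of conventional dendritic cells, which like B cells the sort for CD19-negative, CD11b-negative, CD11c-intermediate and B220-positive cells was set to leave out, is also open, with a list median of -0.092 over members that went both ways (Cd209a higher, the mature dendritic cell gene Fscn1 lower). Further open are a cell state that differs among wild type libraries, whose range was 0.312 of the gap between genotypes, and an effect of SLAMF9 loss, which no test here separates from it. The gap was taken over the 31 genes called in these same data, a choice that widens it. Over 9420 genes at higher levels, differences between wild type libraries correlated with the change from wild type to knockout. The r was -0.309 for admin minus b3, -0.465 for admin minus b4 and -0.227 for b3 minus b4, so b4 lay nearest to the knockout. Pairs of knockout replicates gave 0.184 (1 minus 2), -0.123 (1 minus 3) and -0.262 (2 minus 3). The same libraries enter both the differences and the change between genotypes, so these r describe the libraries and test no cause.

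Hspa1a and Hspa1b were higher in the knockout. Reads shifted from one copy to the other are argued against by the summed values, which rose 13.4-fold. A heat shock response is a candidate explanation: the other 17 heat shock factor target genes tested had a median log2 fold change of 0.132 (95% bootstrap interval 0.045 to 0.308), with 6 higher, 11 not passing and 0 lower. The bootstrap resampled genes and not libraries, so its interval does not measure the spread between libraries. The log2 fold change was positive for 14 of the 17, and Bag3 fell without passing (-0.34, limma adjusted p = 0.0900). Handling that differed between genotypes could give a rise of heat shock genes as well as the knockout, and no label records it. A strain variant on chromosome 17 remains open, with an odds ratio of 1.81 (0.894 to 3.38 by Fisher's exact test) for a call among 85 genes within 1 Mb outside the lists, and 1.10 (0.427 to 2.41) without the H2 genes.

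Igsf9 and Gm7804, on both sides of Slamf9, were higher in the knockout. Flanking DNA of another strain was not decided. The odds ratio for a call within 5 Mb was 1.49 (0.738 to 2.74 by Fisher's exact test, p = 0.203), with 12 of 98 genes called. Igsf9 and Gm7804, the genes to be explained, were among the 12 and raise that ratio. Chance neighbours are not excluded, as 1.01% of tested genes had both nearest neighbours called. That share counts calls in either direction. The share with both neighbours higher can only be as large or smaller, and was not counted. A local effect of the altered allele remains open, and its test decides nothing: the 2 called genes within 20 kb were the genes that prompted it, and Tagln2, at 21.5 kb, did not pass (limma adjusted p = 0.415). The altered exons and read positions were not used here, so these explanations cannot be told apart.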
